A study of Xenopus laevis with 4 samples.

How the data were processed

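RNA of animal and vegetal blastomeres of 8-cell Xenopus laevis embryos was isolated with TRIzol and made into libraries with a NEBNext mRNA kit, per the labels' protocols. Bowtie and DESeq are named, without versions, in the submitters' processing notes. The counting tool, the treatment of reads that match several records, strand and read layout are not given in the sources used here. The authors deposited 1 table in which each record is a RefSeq transcript (11030 protein-coding, 19 non-coding), the mitochondrial genome or a further RNA record named SCP1. Per the file headers it holds a count and an RPKM per library, a record length, and DESeq means, a fold change, a p-value and an adjusted p per record.

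The deposited counts are estimated counts that need not be whole: 1.87% to 2.99% of values above 0 were fractional, and 82.9% to 84.6% were even. The even values leave open that both ends of a fragment were counted, which would make the counting noise larger than the counts imply. The deposited RPKM values were recomputed from count, length and library total, with 100% within 0.1% for values above 1 RPKM, so they hold no further normalization and were not tested. The signal values deposited by the authors are means of counts divided by DESeq size factors, over all libraries and per group, per the file headers. The deposited log2 fold changes were not used, because 350 cells held spreadsheet error text. The deposited fold change (a ratio of DESeq means, vegetal over animal) and the deposited p-values were used only where the authors' deposited table is named. Records were named by RefSeq accession, version ignored, from a gene table of assembly Xenopus_laevis_v10.1, which matched 10200 of 11051 records. Its coordinates were not used, since the authors' reference is not given in the sources used here. No genome was used, so GC content was not analysed here.

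Estimated counts were rounded to whole numbers. Library totals were 37519504 and 36028924 (vegetal 1 and 2) and 37657299 and 38976115 (animal 1 and 2). Records were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 8915. Of the 11051 records, 1128 had no count in any library. The main test was edgeR 4.0.16 quasi-likelihood (glmQLFit and glmQLFTest in the default of this version, TMM scaling, group as the only term, 2 libraries per group) in R 4.3.3, with Benjamini-Hochberg adjusted p below 0.05. The test, samples, gene lists, rule for named genes and alternatives were written before the data were examined. They did not say which form of the quasi-likelihood dispersion to use. That option was settled after both forms had been run: the version's default calls 0 records and the form with bias-adjusted deviances 3. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Normalized counts are CPM from the edgeR function cpm, that is, counts scaled by library size and TMM factor, and intervals from them cover counting and replicate spread between these samples only.

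Gene lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and also with an estimated one, for the 21 lists with at least 5 tested records. The mitochondrially encoded list matched no record, because the table holds the mitochondrial genome as 1 record. List members were also adjusted over the list alone. Symbols were matched without case and copy suffix and through older symbols, and 6 matches to an older symbol of another gene were dropped by name. Lists overlap in membership. The rule named the up to 12 largest changes per direction among called records with a mean of at least 20 normalized counts, every tested member of the vegetal, germ plasm and animal lists, and the 4 smallest adjusted p in each other list. With 0 calls its first part named none. A gene with several records is represented by the one with the highest mean.

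Alternatives were DESeq2 1.42.0 size factors, library totals only, upper-quartile scaling, no low-count filter, a mean of at least 50 normalized counts, the DESeq2 Wald test, limma-voom, the authors' deposited adjusted p, the replicate number as a block, leaving out each library, a glmTreat threshold of 1.5-fold and summing records that share a symbol. Alternatives added after seeing the data were bias-adjusted deviances, DESeq2 and limma-voom with the block, halved counts and removal of the mitochondrial genome and aifm2 records. DESeq2 gave no adjusted p for 1210 records, which were left as such. The fit was tested on simulated counts for the 8915 records with 200 changed by known folds and noise drawn independently for each library. Figures were drawn with matplotlib 3.10.9.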

Results

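RNA was sequenced from blastomeres of 8-cell embryos of the frog Xenopus laevis. The early cleavages of this embryo separate pigmented animal cells, at the pole that later forms ectoderm, from yolk-rich vegetal cells. Embryos were dissociated in saline without calcium and magnesium, and animal and vegetal blastomeres were collected apart. The series held 2 vegetal and 2 animal libraries. The design text calls the replicates biological but does not say whether they came from separate clutches or females, so p-values measure the spread between these samples. The deposited table listed 11051 transcript records, with totals of 37519504 and 36028924 estimated counts in the vegetal libraries and 37657299 and 38976115 in the animal libraries. After a low-count filter, 8915 records were tested. The genome duplication of this species left many genes with an L and an S copy, and these are named by their suffix. Reads from near-identical copies may have been divided between them, so values of single copies are uncertain to that extent.

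The series asked which transcripts differ in level between animal and vegetal blastomeres. Most transcripts of genes listed beforehand as vegetal determinants were far more abundant in the vegetal libraries. Of the 20 tested records on the fixed list of vegetal determinants, 16 were higher in vegetal and 1 was lower by edgeR's quasi-likelihood test adjusted over the list alone. None of the 20 passed when adjusted over all records tested. The median log2 fold change of the list, vegetal over animal, was 2.68, and the median taken between single libraries ranged from 2.35 to 3.08 over the 4 vegetal and animal pairs. The transcription factor vegt, which specifies endoderm and mesoderm, stood at 1593 ± 18.7 CPM (TMM-normalized counts relative to library size; SD, n = 2) in vegetal and 164 ± 59.3 in animal blastomeres for its L copy, a log2 fold change of 3.28 ± 0.38 (SE). The TGF-beta family ligand gdf1.S (Vg1) reached 1009 ± 335 against 43.8 ± 12.6 CPM, a log2 fold change of 4.52 ± 0.45. The Wnt ligand wnt11b.L had a log2 fold change of 3.22 ± 0.50. The ubiquitin ligase gene trim36.L and the kinesin linker gene sybu.S, both linked to dorsal axis formation, had log2 fold changes of 3.56 ± 0.35 and 3.55 ± 0.39. With edgeR's adjustment over the list alone, the adjusted p was 0.00099 for vegt.L, gdf1.S, trim36.L and sybu.S, and 0.0021 for wnt11b.L.

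Further members of this list were also higher in vegetal blastomeres. The log2 fold changes were 3.14 ± 0.50 for sox7.L and 3.12 ± 0.61 for snai1.S, both transcription factor genes, 3.04 ± 0.35 for the ephrin gene efnb1.L, 2.54 ± 0.34 for the homeobox gene otx1.L and 2.32 ± 0.48 for the RNA-binding protein gene bicc1.S. The acyl-CoA synthetase gene acsl1.L and the lipid droplet coat gene plin2.S had log2 fold changes of 2.53 ± 0.28 and 1.46 ± 0.28. The only record of the list that passed as lower in vegetal was dand5.S, which encodes a secreted antagonist of TGF-beta family and Wnt ligands. Whether it belongs on a list of vegetal transcripts was not checked. It stood at 929 ± 243 CPM in animal and 340 ± 82.6 CPM in vegetal blastomeres, and its log2 fold change was -1.45 ± 0.36, with an adjusted p of 0.011 in edgeR over the list alone. The log2 fold changes of rras2.S, kif3b.S and fzd7 were 2.07 ± 1.30, -0.79 ± 0.52 and -0.18 ± 0.30, and these records did not pass. The rras2.S record was close to the floor, at 0.86 ± 0.53 CPM in vegetal and 0.20 ± 0.18 CPM in animal blastomeres.

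Germ plasm transcripts held the largest log2 fold changes of single records on the vegetal and germ plasm lists, although the list median of 1.63 was below that of the vegetal determinants. Germ plasm is the vegetal cytoplasm inherited by the future germ cells. Of 16 tested records, 9 were higher in vegetal by edgeR adjusted over the list alone, 7 did not pass, and none was lower. None of the 16 passed when adjusted over all records tested. The germ plasm transcript germes.L stood at 399 ± 31.2 CPM in vegetal and 4.98 ± 1.13 CPM in animal blastomeres, a log2 fold change of 6.32 ± 0.38, and the lower vegetal library lay 65.2 times above the higher animal library. The scaffold gene grip2.L had a log2 fold change of 6.60 ± 0.81, the translational repressor gene nanos1.L 5.73 ± 0.89, the RNA helicase gene ddx25.L 5.61 ± 0.37, pgat.L (Xpat) 5.60 ± 0.35 and the RNA-binding protein gene dazl.L 4.52 ± 0.34. Those of rtn3.L and velo1.L were 1.81 ± 0.31 and 1.45 ± 0.34. The S copy of rtn3, also on this list but with a lower mean, was at 5.02 ± 0.44. The members that did not pass included ddx4.L (vasa), with 119 ± 2.68 CPM in vegetal and 113 ± 37.6 CPM in animal blastomeres, and the Tudor domain genes tdrd5.L, tdrd6.L and tdrd7.L, with log2 fold changes of 0.24 ± 0.46, 0.15 ± 0.31 and 0.27 ± 0.29. The values for rbpms2.L and tdrkh.L, the other named members that did not pass, were 0.61 ± 0.40 and -0.92 ± 0.55.

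**Figure D1:**
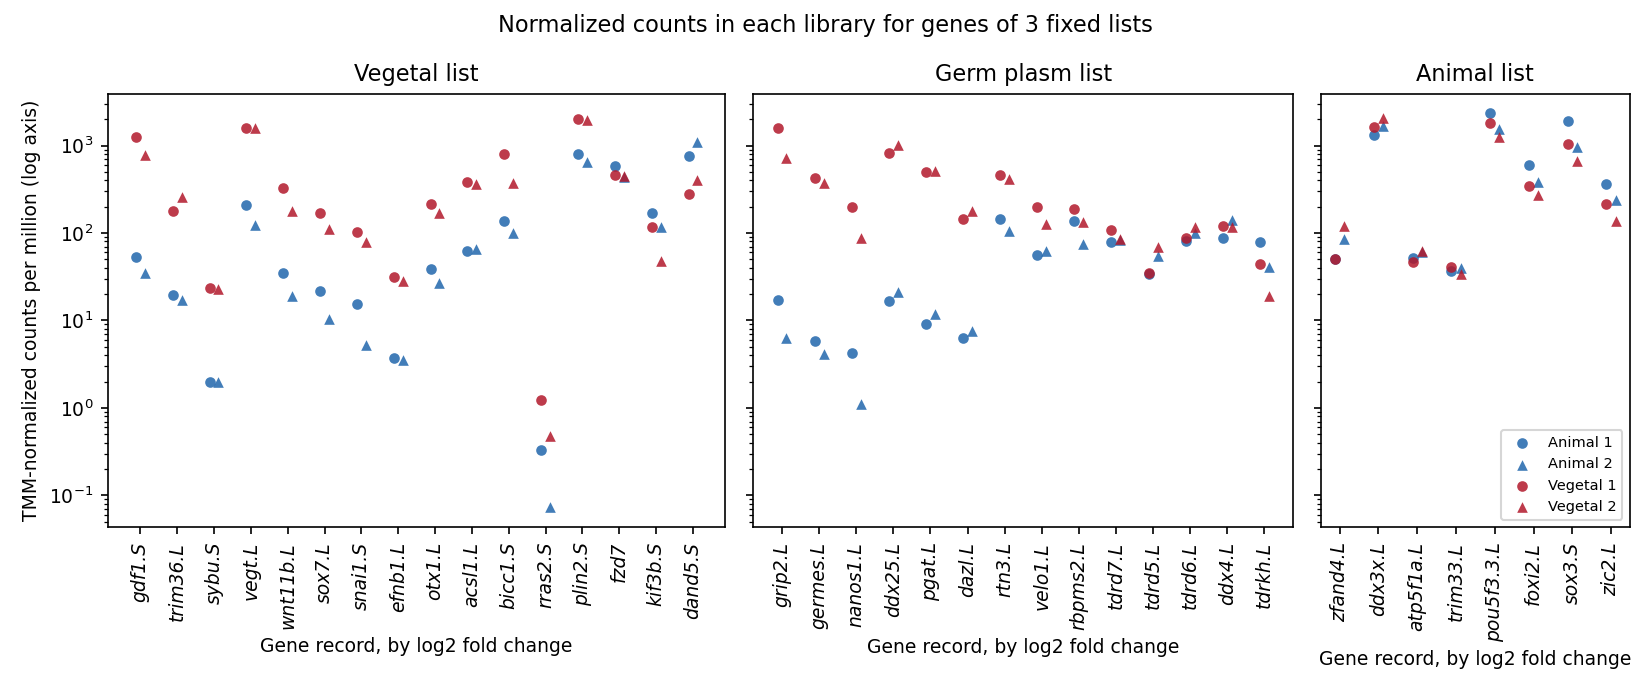
TMM-normalized CPM (log axis) in each of the 4 libraries for the named records of the vegetal, germ plasm and animal lists, ordered by log2 fold change; blue symbols are animal and red symbols vegetal libraries, circles replicate 1 and triangles replicate 2. For germes.L both vegetal libraries lie at least 65.2 times above both animal libraries, while the ddx4.L values overlap.

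Both lists stood apart from the other records in limma's camera test with a preset inter-gene correlation of 0.01. The adjusted p over the 21 lists tested was 2.9e-22 for the vegetal determinants and 1.5e-15 for germ plasm. With a correlation estimated from these 4 libraries, the camera adjusted p was 0.42 and 0.26, and neither list passed. That form of the test takes its degrees of freedom from the 4 libraries, and none of the 21 lists passed it. It had little power for any list, so no conclusion was drawn from it.

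Across all 8915 records, edgeR with group as the only term called 0 records higher in vegetal and 0 higher in animal blastomeres at an adjusted p below 0.05. The smallest edgeR adjusted p was 0.061, shared by germes.L, pgat.L and ddx25.L. At an unadjusted p below 0.05 edgeR counted 242 records higher in vegetal and 67 higher in animal, against 223 per direction by chance if the assumptions of this fit held. That split was 197 to 96 with upper-quartile scaling. Deviations from the group means correlated at 0.71 over records between same-numbered libraries. The libraries may therefore not be independent, and no conclusion was drawn from the 223. DESeq2 called 79 vegetal and 2 animal records, and limma-voom 3 and 0. With the replicate number as a block, all 3 tools called more vegetal records and DESeq2 also many more animal records. Those counts are given in the section on processing, since the labels do not say what the number marks. The authors' deposited table held 43 vegetal and 0 animal records at an adjusted p below 0.05. All 43 were also among the DESeq2 calls, and in all 43 both vegetal libraries lay above both animal libraries. Both comparisons use the libraries by which the 43 were selected, so neither is independent support. Their edgeR log2 fold changes ran from 1.79 to 6.60. In simulated counts with the spread of this fit, edgeR recovered 0 of 50 records changed 2-fold, 18 of 50 changed 4-fold and 49 of 50 changed 16-fold. DESeq2 recovered 3, 37 and 50 of 50 at the same folds. The same simulation gave 15 false calls by edgeR and 60 by DESeq2. In it edgeR recovered 50 of 50 records changed 64-fold. In the data edgeR did not call germes.L, at a log2 fold change of 6.32. The simulated noise was drawn independently for each library, and no power or rate of false calls in these data was read from it. The edgeR counts depended on single libraries: without vegetal replicate 1 the test called 49 vegetal and 234 animal records, and without vegetal replicate 2 it called 28 and 0. Without animal replicate 1 or animal replicate 2 it called 0 in both directions. In such a fit the lone library is assumed to vary like the pair of the other group.

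**Figure D2:**
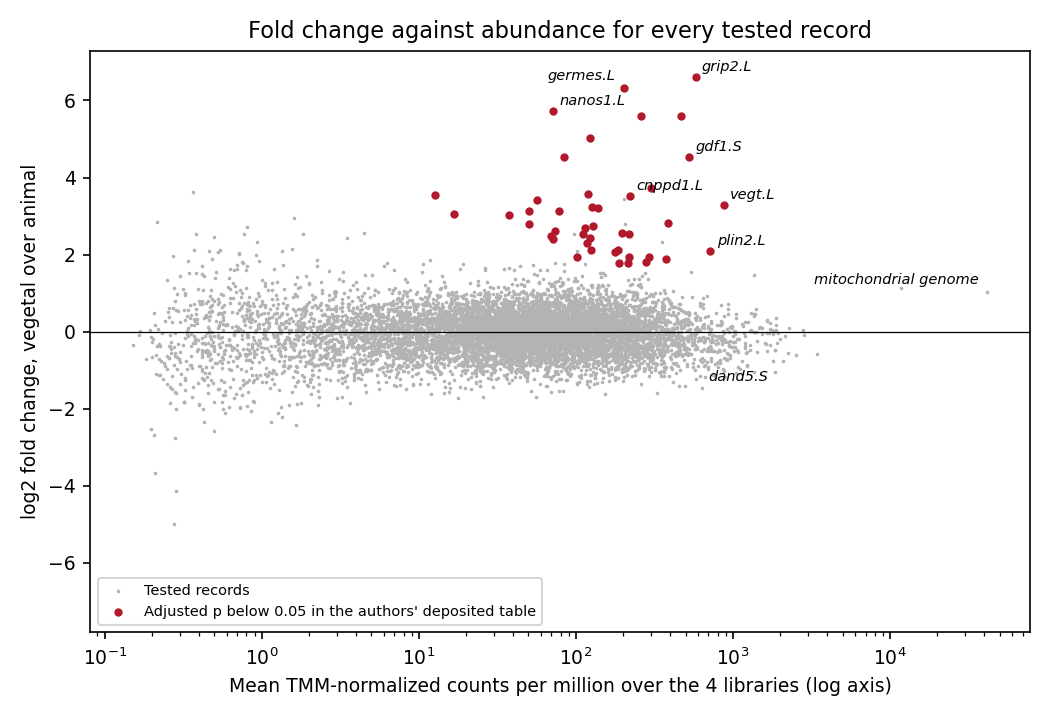
Log2 fold change, vegetal over animal, against the mean TMM-normalized CPM over the 4 libraries (log axis) for each tested record in grey; red points are the 43 records with an adjusted p below 0.05 in the authors' deposited table. The red points all lie on the vegetal side, between 1.79 and 6.60.

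The deposited calls reached beyond the 2 lists, which held 22 of the 43. The proprotein convertase gene pcsk6.L, on the TGF-beta list, stood at 562 ± 118 CPM in vegetal and 42.3 ± 0.51 CPM in animal blastomeres, and its log2 fold change of 3.73 ± 0.33 had an edgeR adjusted p of 0.0037 over that list alone. Records outside every list were chosen after their values were seen. Among these, cnppd1.L, a cyclin domain gene, stood at 407 ± 6.57 against 35.3 ± 0.37 CPM, with an adjusted p of 9.7e-09 in the authors' deposited table. The glycerol kinase gene gk.S had a log2 fold change of 3.42 ± 0.36 and lsm4.S, which encodes an RNA-binding Sm-like protein, 3.02 ± 0.32. The glycolytic gene pgam1 was higher in vegetal blastomeres by DESeq2 for both copies, with edgeR log2 fold changes of 2.69 ± 0.33 for pgam1.L and 2.07 ± 0.31 for pgam1.S.

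Fewer records had wide gaps on the animal side. On the list of 15 tested animal maternal records, 0 passed by edgeR over all records and 0 over the list alone, 2 had an unadjusted p below 0.05 with the animal value higher, and DESeq2 called 0. The list median was -0.30, with 5 records in which both animal libraries exceeded both vegetal libraries, and the camera adjusted p was 0.062, with an adjusted p = 0.42 with an estimated correlation. The camera adjusted p was 0.047 with library totals as the only scaling and 0.046 with limma-voom weights. The 2 records with an unadjusted p below 0.05 were copies with a lower mean and are not among those named here. The transcription factor genes zic2.L, foxi2.L and sox3.S had log2 fold changes of -0.78 ± 0.38, -0.67 ± 0.36 and -0.77 ± 0.45. Those of pou5f3.3.L, trim33.L and atp5f1a.L were -0.34 ± 0.36, -0.05 ± 0.29 and -0.03 ± 0.31, while ddx3x.L and zfand4.L were at 0.31 ± 0.29 and 0.31 ± 0.53. The 2 animal calls of DESeq2 without the replicate block were dand5.S and nudt9.L, a nudix hydrolase gene chosen after its values were seen, at 23.3 ± 0.92 against 8.42 ± 0.18 CPM. Their DESeq2 adjusted p was 0.032. Over all tested records, 93 had both vegetal libraries at least 2-fold above both animal libraries and 21 had the reverse. The counts were 31 and 4 at a gap of 4-fold and 13 and 3 at 8-fold. Among records with a mean of at least 5 CPM, the largest animal gap was 2.65-fold, for nudt9.L. The animal gaps of 4-fold and 8-fold were therefore all in records of lower abundance. Without a minimum gap, 18.0% had every vegetal library above every animal library and 16.5% the reverse. The share would be 16.7% per direction by chance if the 4 libraries were exchangeable. Vegetal replicate 1 lay closer to animal replicate 1 (SD of the log2 difference 0.57) than to vegetal replicate 2 (1.25). The 16.7% is therefore not a fair baseline here, and no conclusion was drawn from it.

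Among the other lists, camera with the preset correlation called 7. None of these passed with an estimated correlation, a setting with little power here. In the cytoskeleton list the median of 42 records was -0.36 (camera adjusted p 0.0076, and adjusted p = 0.42 with an estimated correlation). The actin-binding tropomyosin gene tpm3.S, the tubulin gene tubb4b.S and the keratin genes krt18.1.L and krt19.L had log2 fold changes of -1.18 ± 0.46, -0.84 ± 0.31, -0.72 ± 0.31 and -0.89 ± 0.44, with 0 of 42 called by edgeR over the list alone or by DESeq2. Lysosome and yolk genes had a median of 0.40 over 23 records (camera adjusted p 0.027, and adjusted p = 0.42 with an estimated correlation), led by lamp1.S, a lysosomal membrane protein gene, at 1.06 ± 0.28. For chromatin genes the median was -0.38 over 31 records and for proteasome genes -0.18 over 46, each with a camera adjusted p of 0.038, and with an adjusted p = 0.78 and 0.42 with an estimated correlation. The chromatin remodelling genes chd4.L and smarca4.S had log2 fold changes of -0.87 ± 0.68 and -0.96 ± 0.70, and the proteasome gene psmc3.S -1.24 ± 0.50. The chromatin call rested on vegetal replicate 2, without which the adjusted p was 0.83 and the direction turned. The cytoskeleton call was lost without vegetal replicate 1, at an adjusted p of 0.13. The lysosome call was lost without vegetal replicate 1, vegetal replicate 2 or animal replicate 2, at adjusted p values of 0.059, 0.095 and 0.11. The proteasome call was lost without vegetal replicate 1 or animal replicate 2, at 0.29 and 0.44, and the chromatin call also without animal replicate 2, at 0.11.

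The 3 remaining camera calls shared members with the vegetal list. Lipid droplet and fatty acid genes had 5 of 27 records higher in vegetal by edgeR over the list alone, and 4 of these are copies of plin2 and acsl1. The fifth was dgat2.L, a triglyceride synthesis gene, at 1.44 ± 0.30. Without the shared records the lipid median was -0.09 and the camera adjusted p was 0.87, against 0.038 with them and 0.42 with an estimated correlation. In the FGF, Notch and related signalling list, 2 of 23 passed over the list alone, efnb1.L and the receptor gene fgfr2.L at 1.59 ± 0.30. Its camera adjusted p was 0.038, 0.42 with an estimated correlation and 0.14 without the shared record. In the list of maternal and pluripotency transcription factors, both vegt copies and otx1.L passed over the list alone while the list median was -0.47 (camera adjusted p 0.038, and adjusted p = 0.78 with an estimated correlation). Without those 3 records the median of the remaining 41 was -0.56 and the camera adjusted p was 0.0024. It was 0.89 with an estimated correlation, and that call was lost without animal replicate 1. Testing lists without shared records was chosen after the data were seen. All 3 calls also depended on single libraries. Without vegetal replicate 1, vegetal replicate 2, animal replicate 1 or animal replicate 2 the signalling list had adjusted p values of 0.14, 0.19, 0.12 and 0.11. The transcription factor list had 0.13, 0.31 and 0.83 without the first 3 of these, and the lipid list 0.27 and 0.19 without vegetal replicate 1 and animal replicate 2.

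**Figure D3:**
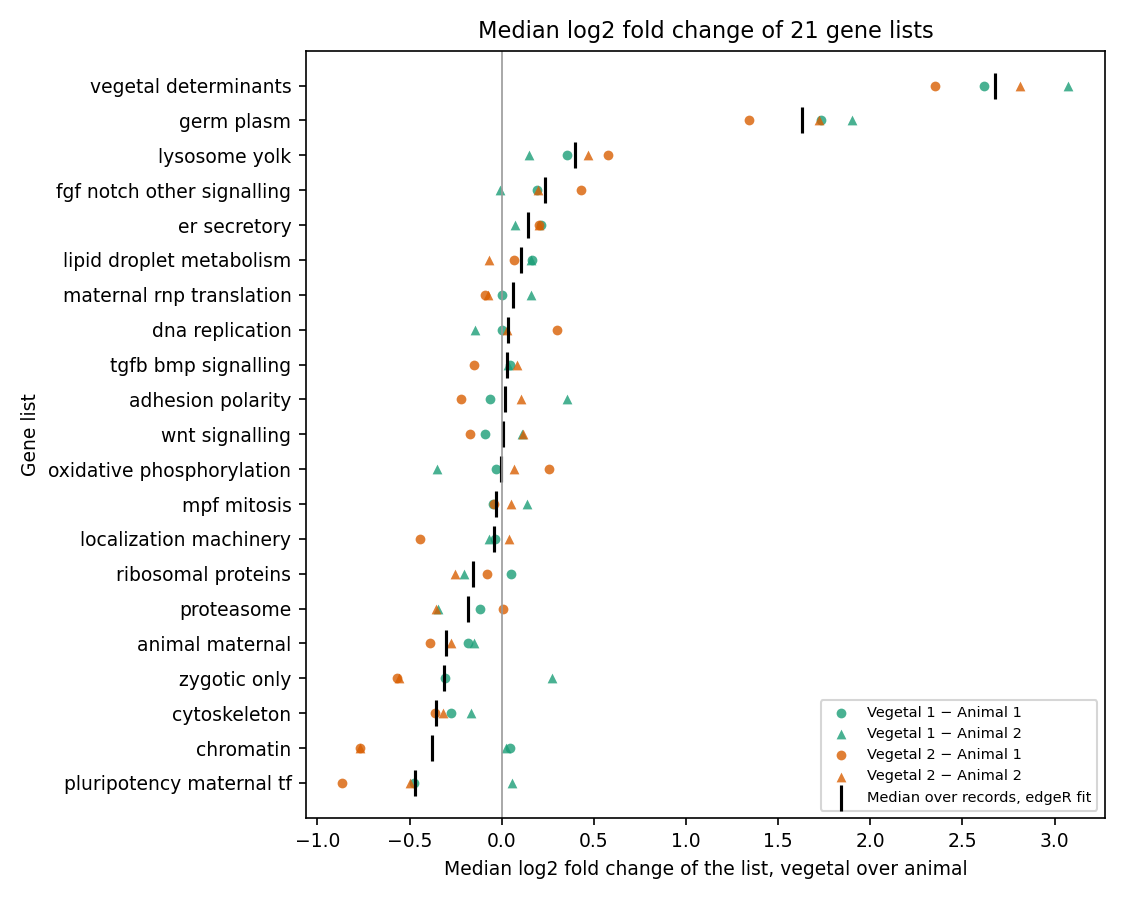
Median log2 fold change, vegetal over animal, of the 21 gene lists with at least 5 tested records; the black bar is the median over the records of a list in the edgeR fit, and coloured symbols are medians of the differences in log2 CPM between 1 vegetal and 1 animal library. The vegetal determinants (2.68) and germ plasm (1.63) lie apart from the other lists, whose medians run from -0.47 to 0.40.

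The other 11 lists tested had no camera call. Medians were 0.14 for secretory pathway genes (camera adjusted p 0.11), -0.16 for ribosomal proteins (0.11), 0.02 for adhesion and polarity (0.40), 0.03 for TGF-beta and BMP signalling (0.40), -0.32 for genes known as zygotic (0.40), -0.04 for RNA localization factors (0.65), and -0.004 for nuclear genes of oxidative phosphorylation (0.68). They were 0.03 for DNA replication (0.89), 0.01 for Wnt signalling (0.89), 0.06 for maternal RNA-binding and translation factors (0.95) and -0.03 for mitosis genes (0.95). For Wnt signalling the median was positive while camera and the mean of -0.03 pointed to animal, and the translation list had a mean of -0.06. Among these lists edgeR over the list alone called only pcsk6.L and gdf1.S of the TGF-beta list. Of the mitosis and replication genes, aurka.S stood at 360 ± 29.1 CPM in vegetal and 668 ± 45.5 CPM in animal blastomeres, and chek1.S at 111 ± 40.3 and 44.4 ± 15.5 CPM. Zygotic genes had 14 of 44 records above the filter and a median of 1.38 CPM in vegetal and 1.09 CPM in animal blastomeres, so their median level and their median log2 fold change pointed in opposite directions. With upper-quartile scaling the medians of the adhesion, TGF-beta and Wnt lists turned negative, at -0.02, -0.01 and -0.03. Leaving out a library brought some of these lists past the camera threshold. Without vegetal replicate 2 the adjusted p was 0.049 for adhesion and polarity and 0.0082 for oxidative phosphorylation. Without animal replicate 1 it was 0.024 for adhesion and polarity, 0.049 for oxidative phosphorylation, 0.012 for ribosomal proteins and 0.049 for TGF-beta and BMP signalling.

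Few records of the blood and liver list and of the follicle and ovary list passed the low-count filter, and which cells these transcripts came from was not tested. Of 14 blood and liver records, 1 passed the filter, the globin record hba-l5.L, at 76.9 ± 44.9 CPM in vegetal and 87.6 ± 37.1 CPM in animal blastomeres, a log2 fold change of -0.19 ± 0.55. Of 10 follicle and ovary records 2 passed it, and these went opposite ways. The steroid synthesis gene cyp17a1.L was one of them, at 419 ± 64.1 against 162 ± 0.50 CPM, with an edgeR adjusted p of 0.0094 over the list alone and 0.67 over all records. The other, foxl2.S, a transcription factor gene, was close to the floor, at 0.14 ± 0.20 CPM in vegetal and 0.43 ± 0.26 CPM in animal blastomeres, and did not pass. The record of the whole mitochondrial genome took 4.17% and 7.03% of counts in the vegetal libraries and 2.66% and 2.87% in the animal libraries, a log2 fold change of 1.02 ± 0.27 with an edgeR adjusted p of 0.91. Libraries of a group did not lie closest to each other. The SD over records of the log2 difference was 1.25 between both vegetal libraries and 0.97 between both animal libraries. From vegetal replicate 1 it was 0.57 to animal replicate 1 and 0.96 to animal replicate 2, and from vegetal replicate 2 it was 1.46 and 1.005.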

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

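Bias-adjusted deviances, DESeq2 or limma-voom with the block, halved counts and removal of the mitochondrial genome and aifm2 records were chosen after seeing the data; the other alternatives were planned. Against 0 vegetal and 0 animal calls by edgeR (242 and 67 at an unadjusted p below 0.05), other tools gave more vegetal calls. These were 3 without a low-count filter, 3 with limma-voom, 3 with bias-adjusted deviances (germes.L, ddx25.L and pgat.L), 79 vegetal and 2 animal with the DESeq2 Wald test, and 43 vegetal in the authors' deposited table. The numbers of list members called, against 0, were 3, 3, 3, 30 and 23. The cause was not tested. The DESeq2 calls held all 43 records of the deposited table, which rests on the same libraries. Both scaling factors other than TMM, library totals, the stricter filter, the 1.5-fold threshold, summed copies, halved counts and removal of the mitochondrial records left both counts at 0.

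Leaving out 1 library moved the vegetal count over 0 to 49, the animal count over 0 to 234 and the list members called over 0 to 42. The lone library is then assumed to vary like the pair of the other group. The 49 and 234 calls came without vegetal replicate 1, and 43 of the 49 were in the authors' deposited table. Without vegetal replicate 2 there were 28 vegetal calls, 26 of them in that table. The cause was not tested.

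The number of lists called by camera, 9, was 5 without a filter, 3 with copies summed, 0 with an estimated correlation, and 3 to 11 over the leave-one-out fits. The vegetal and germ plasm calls were lost only with the estimated correlation, which with 4 libraries had little power for any list. The adjusted p of the chromatin list ran from 1.9e-04 to 0.83 over the leave-one-out fits, and its direction turned without vegetal replicate 2. The cause was not tested. Camera was not run for DESeq2, the deposited table, the 1.5-fold threshold or bias-adjusted deviances. Over the list alone, vegetal determinants gave 12 to 16 records and germ plasm 8 to 11 under every alternative run. The median log2 fold change of both lists together, 2.54, moved by less than its SD of 0.31 over the 4 library pairs in each alternative. With copies kept apart, sign changes among at most 105 named records occurred only in leave-one-out fits (at most 5), and in none of the 21 vegetal and germ plasm records called by DESeq2. The pseudocount alternative did not apply, since counts were deposited.

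The labels share replicate numbers, but nothing says that a number marks a clutch or day, and with 2 pairs the numbers were not taken to pair the libraries. Deviations from the group means correlated at 0.71 over records between same-numbered libraries. With the replicate block edgeR called 13 vegetal and 0 animal records and 10 list members, and camera called 5 lists. DESeq2 with the block called 419 and 348 records and 105 list members, and limma-voom with the block 25 and 0 and 19 list members. In counts simulated with the spread of the fit with the block, edgeR recovered 9 of 50 records changed 2-fold and 45 of 50 changed 4-fold, with 12 false calls, and DESeq2 recovered 13 and 47, with 37 false calls. This simulation also drew noise independently for each library, so its counts do not carry over to these data.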

Other observations

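The tests of scaling and of the aifm2 record were chosen after the result was seen; the tests of record length were fixed before it, although some long records had by then been seen to be low in vegetal replicate 2. Records outside the rule for named genes were chosen after their values were seen.

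Copies of a gene on the L and S subgenomes were compared where both were tested, in 1408 pairs. DESeq2 called at least 1 copy higher in vegetal blastomeres in 18 pairs and both copies in 6 of these, acsl1, bicc1, pgam1, plin2, rtn3 and vegt. In the other 12 pairs the uncalled copy also had a positive log2 fold change, with a median of 0.87 and a range from 0.26 to 1.52. Some copies differed. The germ plasm gene rtn3 had a log2 fold change of 5.02 ± 0.44 (SE) for the S copy and 1.81 ± 0.31 for the L copy. The gene tob2, a member of the family of antiproliferative Tob proteins, stood at 2.80 ± 0.37 for L and 0.31 ± 0.45 for S, and the ubiquitin ligase gene rnf103 at 2.48 ± 0.33 and 0.61 ± 0.32. The difference between copies was not tested in a model, and reads divided between near-identical copies would bring their values together.

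Further vegetal calls of the authors' deposited table lay outside the fixed lists, and the values given for them are those of edgeR. The fatty acid elongase gene elovl1.S and the acyl-CoA synthetase gene acsbg2.L had log2 fold changes of 2.12 ± 0.30 and 1.94 ± 0.32. The transcription factor gene irf8.L was at 2.62 ± 0.32, the actin nucleator gene spire1.S at 2.57 ± 0.46 and the calcium pump gene atp2a3.L at 2.30 ± 0.28. On the animal side, pdhx.L, a component of the pyruvate dehydrogenase complex, stood at 35.7 ± 1.43 CPM (SD, n = 2) in animal and 13.5 ± 3.32 CPM in vegetal blastomeres, and it did not pass (adjusted p 0.91 by edgeR and 0.070 by DESeq2). No theme was tested for enrichment among these records.

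Wide gaps between the groups lay mostly on the vegetal side, 93 records against 21 at a gap of at least 2-fold, and 25 of the 93 were vegetal or germ plasm list members. A common factor of 0.27 on the log2 scale between the groups evened these counts, at 67 and 71, so a scaling error remains open for gaps of 2-fold, although the 4 scalings spanned only 0.033. With that factor 28 vegetal and 5 animal records still had a gap of at least 4-fold, a ratio of 5.60, which argues against scaling as the whole cause of the wider gaps. Before that factor, the largest animal gap among records with a mean of at least 5 CPM was 2.65-fold, so the wider animal gaps were in records of low abundance. On log2 CPM with a prior count, the gaps of at least 2-fold numbered 92 and 18, and 94 and 17 (a ratio of 5.53) once each library's trend on record length was removed. That trend moved the difference between groups by a median of 0.018 and at most 0.29 on the log2 scale over all tested records, and by at most 0.09 among the vegetal gap records, which with the kept ratio argues against it as the whole cause, while GC content and a biological asymmetry of maternal RNA between the poles remain open.

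Vegetal replicate 2 differed from vegetal replicate 1 with an SD of 1.25 on the log2 scale over records. A smooth trend on record length removed 0.189% of that variance, which argues against a smooth length bias as the cause. Vegetal replicate 2 also had 9017 records above 0, against 9452 in vegetal replicate 1 and 9509 and 9491 in the animal libraries, and its 10 most abundant records took 11.03% of counts, against 7.45%, 5.86% and 5.84%. That higher share was mostly the mitochondrial genome record, at 7.03% against 4.17%, 2.66% and 2.87%. The aifm2.S record added 2.09% against 1.16%, 0.658% and 0.837%, so the share does not show that other records were more concentrated. Deviations from the group means correlated at 0.71 over records between same-numbered libraries, so the animal replicates shared part of this difference. A fault confined to vegetal replicate 2 would not give that shared part. A difference in RNA or library quality and a difference between clutches, for which the labels give no information, remain open.

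The record of aifm2.S, a nuclear gene for a flavoprotein, took 1.16% and 2.09% of vegetal counts and 0.658% and 0.837% of animal counts. Its ratio to the mitochondrial genome record was 0.277 and 0.297 in vegetal and 0.247 and 0.291 in animal libraries. Only 0.157% of tested records (14, aifm2.S included) had a ratio to that genome that varied as little over the 4 libraries. A candidate explanation is that mitochondrial reads were counted on the aifm2 record. A nuclear transcript distributed like mitochondria would look the same, and the reads that would tell them apart were not used here.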
